A study of Mus musculus with 4 samples.

How the data were processed

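H3K56ac ChIP-seq, which maps histone H3 acetylated at lysine 56, was run on murine pancreatic ductal adenocarcinoma (PDAC) lines derived from Kras-driven tumours. Peak lists of 3 libraries were analysed, with 1 library in each group. The groups were a Sirt6 wild-type line (WT), a Sirt6 knockout line (KO) and the same knockout line engineered to express wild-type Sirt6 again (restored). The series has 4 samples, and the whole-cell extract of the WT line was not analysed here. Groups were taken from the sample labels. For the restored cells the title, description and design text name wild-type Sirt6, while the treatment protocol writes "Sirt6 KO + Sirt6 KO"; the former was followed, and every restored comparison rests on it. The labels name different lines for the WT and KO cells, so genotype and line go together in every comparison with WT, and only KO against restored is a comparison within a line.

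Reads were aligned with BWA 0.5.9 to mm9, Picard was used, and peaks were called with MACS2 2.0.10, per the submitters' processing notes. Per the file headers, peaks were called on each library by itself with MACS2 2.0.10.20120913, without a control file, at a q cutoff of 0.01, with broad calling off, a tag size of 25 bp, 1 tag kept per position and a regional background over 10 kb. The deposited signal value of each peak is its summit pileup, the coverage by extended fragments at the summit, in whole numbers and not scaled to depth. The deposited fold of each peak is the ratio of that pileup to a local background estimated by the authors' caller from the same library. The authors' −log10 p-value and −log10 q-value of each peak test the summit against that local background. The deposited positions, with starts counted from 1, are in mm9 as given and were not converted.

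Per the file headers, the libraries held 19972013 (WT), 19734112 (KO) and 20100038 (restored) tags, of which 19319155, 19059445 and 19444128 remained after repeated positions were removed. The lowest and highest of these depths differed by 2.02%. At a summit with 40 fragments, the median in KO, a difference between libraries of less than 1.55 times lies within counting error, while medians over many regions are far more precise. A missing peak means only that a site missed the authors' threshold. No library was repeated, so no test across samples was possible and no p-value across regions is given. Shares carry 95% Clopper-Pearson intervals, which cover counting error only. Medians of pileup carry 95% intervals from 1000 resamplings of 10 Mb blocks, which cover the spread along the genome in these libraries only. Where stated, single regions were resampled instead of blocks, which treats neighbouring regions as independent.

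Peaks on chromosomes 1 to 19, X and Y were kept, and peaks on unplaced sequences were set aside. A peak counted as shared when a peak of the other list overlapped it by at least 1 bp. The share of overlap that chance gives was found from 100 circular shifts of the counted list along each chromosome, with the other list left in place. The 3 lists were also merged into 1 set of regions, and a region was present in a library when it held at least 1 of its peaks. KO peaks with and without a WT peak were compared within 10 equal classes of the authors' q in the KO list (strength classes), since weak peaks drop under a threshold by chance, and classes with fewer than 20 peaks on either side were left out of the mean difference. The authors' fold, p and q describe or rank peaks within a list, and their values at single sites were not compared between lists. Median folds are printed for each list, and a q threshold was also applied to all lists. The local background of each peak was derived from its pileup and fold.

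Pileups were compared between libraries only in regions present in all 3 lists, as log2 of the highest summit pileup divided by the number of remaining tags. This comparison was chosen after the files had been seen, because the pileup proved to be unscaled. Per the file headers the fragment lengths were 229 bp (WT), 219 bp (KO) and 222 bp (restored). Longer fragments raise the pileup from the same tags, and pileups were not scaled to fragment length. Counting error was simulated with 100 Poisson draws around the mean of the 3 libraries, and for restored against KO again with their median shift put in. A region was called isolated when every peak in it had a local background within 2% of the genome-wide level of its library, meaning no enriched surroundings. Runs of 4 or more neighbouring regions of one kind were counted against 1000 permutations of the kinds within each chromosome. Medians of 10 Mb bins are given for bins with at least 20 regions. Calculations used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data: all 7 of 7 presence classes came back with the exact number of regions among 13302 simulated regions, 3467 of 3467 simulated KO peaks without a WT peak were recovered, and a simulated shift of 0.4 on chromosome 5 was measured as 0.39 over 1651 regions.

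Alternatives fixed before the data were examined were a q at or below 1e-10, chromosomes 1 to 19 only, equal list lengths, the stronger 50% of each list as present with absence of any peak, sharing within 1 kb, and overlap of at least 50% of a peak. For a q of 1e-10 every list was cut, so a peak with a weaker q counted as absent. The stronger 50% was cut at the median q of each list, so this threshold differed between lists. Regions named by position are, for each of 4 kinds of presence, the 5 with the highest authors' fold, a rule fixed before the data were examined for the case that no mm9 annotation was at hand. The gene table used here belongs to another build (GRCm38), so peaks were not assigned to genes. Counts of promoters and of the members of gene lists, and values for Lin28b and the other genes that were to be named, are therefore not reported here.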

Results

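Sirt6 is a nuclear deacetylase of histone H3, and lysine 56 is among the residues it acts on. H3K56ac was profiled by ChIP-seq in 3 libraries of murine PDAC cells, 1 each of the WT line RP07, the KO line SK03 and the KO line with wild-type Sirt6 restored. The series title links the tumour-suppressor role of Sirt6 to control of Lin28b, and the comparisons ask where acetylation differed without Sirt6 and where it returned with it. The lists held 35178 WT, 40282 KO and 34202 restored peaks from 19319155, 19059445 and 19444128 tags, and they covered 18.8, 20.6 and 16.9 Mb. Peaks were narrow, with median widths of 446, 423 and 411 bp, and their median summit pileups were 41, 40 and 39 fragments. The authors' median fold over the local background was 5.00 in WT, 4.67 in KO and 4.92 in the restored library. There were no replicates, so no difference below could be set against a spread between cultures.

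Most H3K56ac peaks of each list had a counterpart in the others, and the peaks that had none were mostly weak. Of 49577 merged regions, 22698 (45.8%, 95% interval 45.3 to 46.2) held a peak in all 3 lists. These common regions had a median KO pileup of 53 fragments, and 83.9% of them passed a q of 1e-10 in KO. Regions held by KO only numbered 7411 (14.9%, 14.6 to 15.3), and those held by WT only numbered 7358 (14.8%, 14.5 to 15.2). A further 5494 regions (11.1%, 10.8 to 11.4) were in KO and restored but not WT, the pattern that follows the line. Only 1331 regions (2.68%, 2.54 to 2.83) were in WT and restored but not KO. The remaining regions were in restored only (2720) or in WT and KO (2565). Regions of KO only had a median pileup of 25 fragments, and 11.3% of them passed a q of 1e-10, against 43.4% of the regions in KO and restored.

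**Figure D1:**
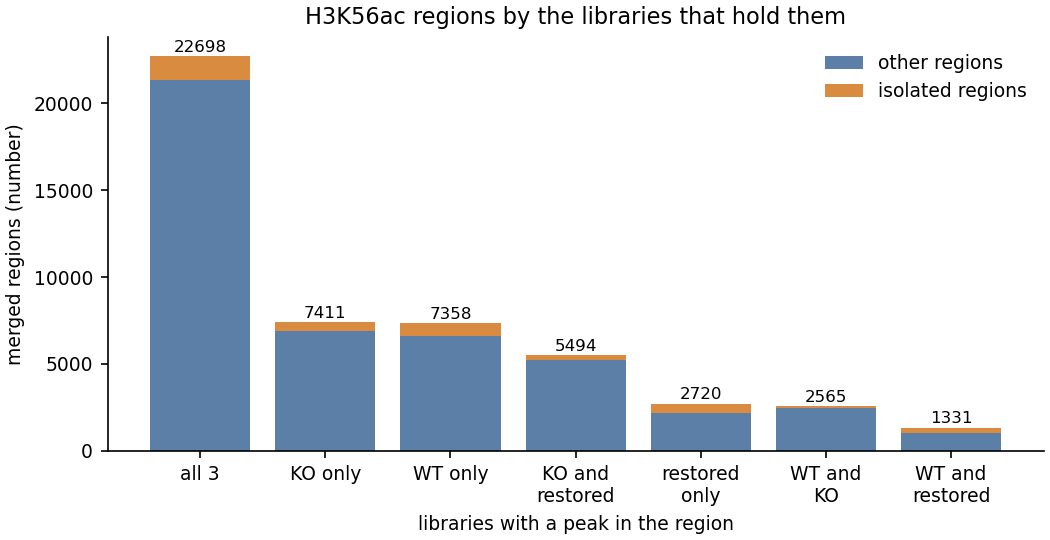
Number of merged H3K56ac regions (y axis) by the libraries that held a peak there (x axis), with 1 library per group. The orange part of each bar is isolated regions, whose surroundings were at the background level. The 22698 regions common to all 3 lists exceed every other kind, and the 1331 regions of WT and restored are the fewest.

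KO against WT addresses where H3K56ac differs in cells without Sirt6. In KO, 13287 peaks (33.0%, 32.5 to 33.4) had no WT peak, and in WT, 8808 peaks (25.04%, 24.6 to 25.5) had no KO peak. Peaks present on one side only were low, with median pileups of 28 in KO and 26 in WT, against 49 and 48 for shared peaks. Chance overlap was 1.33% for KO peaks and 1.498% for WT peaks. The excess on the KO side was there at a q of 1e-10 (5824 against 4831), where a weaker peak in the other list counted as absent. It was also there when only the stronger 50% of each list counted as present (1995 against 1002). That cut was the median −log10 q of each list, 12.05 in KO and 13.64 in WT, so it admitted weaker peaks in KO. Equal list lengths, which draw such counts together by construction, gave 9205 and 9520. Shared peaks numbered 26995 in KO and 26370 in WT, so the excess largely restates the longer KO list. Across the 22698 common regions the KO pileup was 1.01 times the WT pileup at the median (log2 difference 0.02, 95% interval -0.01 to 0.05). This value is not scaled to fragment length, which was 219 bp in KO and 229 bp in WT.

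Single regions differed widely around that median. The SD of the log2 difference between KO and WT was 0.49, against 0.31 from counting error alone. The pileup was over 2-fold higher in KO at 788 common regions and over 2-fold lower at 377, where counting error alone gave means of 56.5 and 55.7. The 3 regions with the highest ratio, chosen after their values were seen, were on chromosomes 3 and 5. At chromosome 3, positions 7366236 to 7367307 (mm9), the summit held 17 fragments in WT, 108 in KO and 97 in the restored library, a KO to WT ratio of 6.44 (3.84 to 11.5, counting error only). At chromosome 5, positions 135462173 to 135465501, the values were 27, 160 and 146 fragments. In the other direction, the region at chromosome 10, positions 33926184 to 33927698, held 115 fragments in WT, 13 in KO and 21 in the restored library, and WT was 8.73 times KO (4.91 to 16.9). The regions at chromosome 13 from 19710858 to 19711683 and chromosome 2 from 91034605 to 91035600 were also lower in KO, with 103 against 18 and 83 against 15 fragments. At each of these 5 regions the restored library was closer to KO than to WT.

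The KO to WT difference was not spread evenly over the genome but followed whole chromosomes. On chromosome 5 the median KO pileup in common regions was 1.38 times WT (log2 0.46, 0.42 to 0.50), and on chromosome 3 it was 1.28 times (0.36, 0.31 to 0.39). Every 10 Mb bin on those chromosomes, 16 of 16 each, had a median above 0. Chromosomes 6 (0.20) and 17 (0.19) were also higher in KO. Chromosomes 18 (-0.23), 8 (-0.21), 14 (-0.17) and 11 (-0.17) were lower in KO, with 0 bins above 0. Chromosome 4 was split: up to 100 Mb the median was -0.35 (-0.42 to -0.25) and from 110 Mb it was 0.25 (0.21 to 0.27), a division chosen after the bins were seen. KO peaks per WT peak were 1.36 on chromosome 5 and 1.33 on chromosome 3, and the ratio was lower where the pileup was lower. It was 1.00, 1.02, 1.03 and 1.06 on chromosomes 14, 18, 8 and 11, and the part of chromosome 4 up to 100 Mb held 962 KO and 917 WT peaks. These ratios lie below that of the whole lists (40282 KO and 35178 WT peaks), although KO did not hold fewer peaks than WT there.

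**Figure D2:**
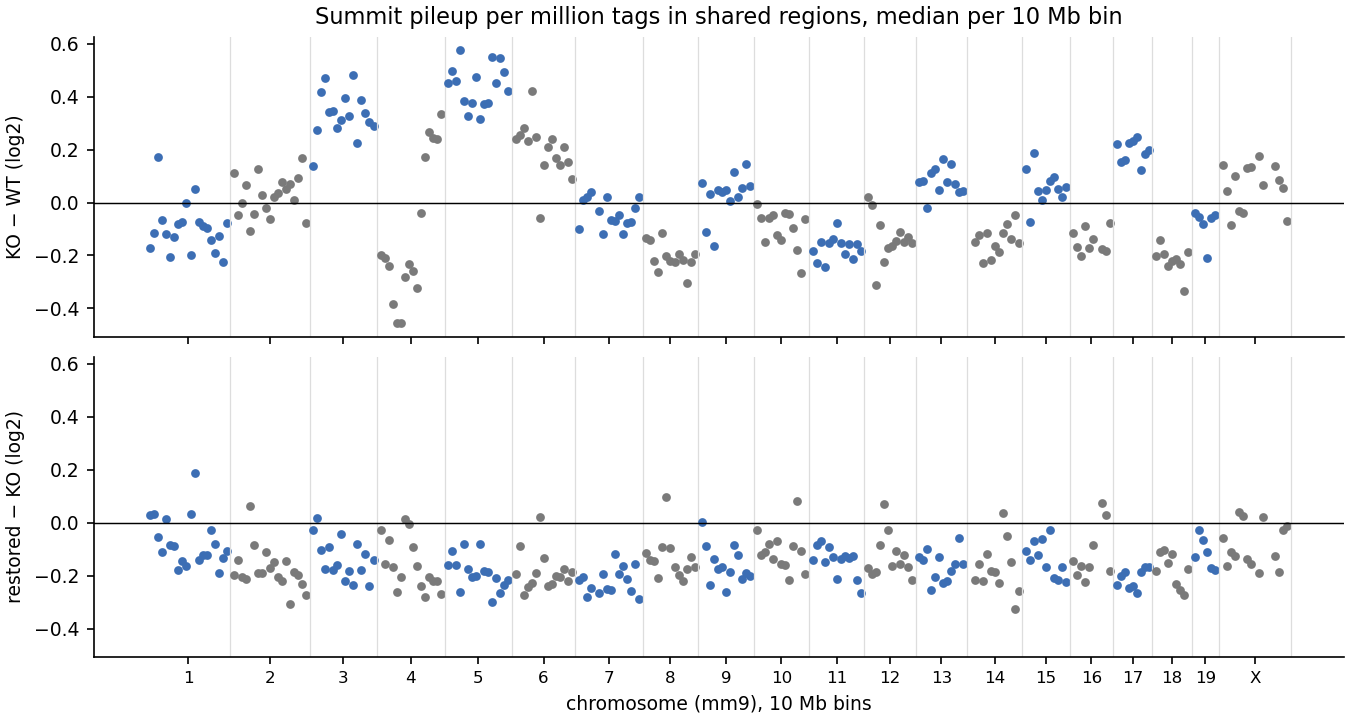
Median log2 difference in depth-scaled summit pileup in common regions, for 10 Mb bins with at least 20 regions along the mm9 chromosomes (x axis, colours alternate by chromosome); the upper panel is KO minus WT and the lower panel restored minus KO. Chromosome 5 (median 0.46) and chromosome 3 (0.36) lie above 0 in every bin of the upper panel and chromosome 4 changes sign along its length, while the lower panel has no such steps and lies around -0.17.

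KO against restored asks which sites respond to the return of Sirt6 within the same line. These lists were the most alike, with a Jaccard index of covered bases of 0.613, against 0.516 for KO with WT and 0.539 for WT with restored. In KO, 10434 peaks (25.9%, 25.5 to 26.3) had no restored peak, while only 4236 restored peaks (12.4%, 12.04 to 12.7) had no KO peak. The counts were 4978 and 2374 at a q of 1e-10, and 688 and 292 when only the stronger 50% of each list counted as present. The latter cut was a −log10 q of 12.05 in KO and 12.80 in restored, so it admitted weaker peaks in KO. Equal list lengths, which again draw the counts together, gave 6326 and 5896. Shared peaks numbered 29848 in KO and 29966 in restored, so the excess of unmatched KO peaks largely restates the longer KO list. In common regions the restored pileup was 0.887 times the KO pileup at the median (log2 -0.17, -0.18 to -0.16), and it was lower at 72.6% of them. Scaled to isolated regions, an alternative chosen after the data were seen, the log2 difference was -0.30. The SD of the difference, 0.31, equalled that of counting error alone (0.31), so single common regions could not be told from a uniform shift by their spread. As sets they differed: the median was 0.12 (0.10 to 0.15) in isolated common regions and -0.19 (-0.19 to -0.18) in the others. Pileups were over 2-fold higher in restored at 23 regions and over 2-fold lower at 131. Counting error with the shift of the median put in gave means of 21.5 (10 to 35 over 100 draws) and 187 (162 to 221). Neither count exceeded it, and the 131 lay below all draws. Common regions needed a peak in each list, a threshold that the draws did not apply. The 9976 merged regions in KO but not restored are outside this comparison, so it cannot exclude loss at single sites. Of the 23 regions 13 were isolated, and of the 131, 2 were. The region with the largest drop, again chosen by its value, was at chromosome 18, positions 77285488 to 77286585, where KO held 64 fragments, restored 18 and WT 41, so KO was 3.63 times restored (2.12 to 6.50). At chromosome 7, positions 25118096 to 25119045, the KO pileup of 72 fell to 23 in the restored library, near the 16 of WT. The largest gain was at chromosome 10, positions 50849890 to 50850288, with 21 fragments in KO, 68 in restored and 62 in WT.

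Regions in KO only are those that a site dependent on the loss of Sirt6 and reversible on its return would give. The 5 with the highest authors' fold were at chromosome 16 from 75593187 to 75593631, chromosome 9 from 94208904 to 94209151, chromosome 17 from 22962078 to 22962331, chromosome 2 from 49922003 to 49922631 and chromosome 7 from 140377825 to 140378210. Their pileups were 33, 32, 30, 30 and 29 fragments, and the authors' folds ran from 10.5 down to 9.20. All 5 stood alone in surroundings at the background level, which a ranking by fold over the local background favours. Of all KO-only regions 6.99% were isolated. KO-only regions numbered 7411, against 1331 of WT and restored. A kind that needs a peak in 1 list is favoured over a kind that needs 2, and the same order held for WT only against KO and restored (7358 and 5494) and for restored only against WT and KO (2720 and 2565). For KO only and WT and restored the counts were 3323 and 1014 at a q of 1e-10, 4240 and 1917 with equal list lengths, and 3461 and 856 when a peak within 1 kb counted as shared. The 3323 include regions where another list held a weaker peak, while 838 of the 7411 regions passed that q in KO. When only the stronger 50% of each list counted as present, 346 KO-only regions and 90 of WT and restored were left. KO-only regions outnumbered those of KO and restored in the main lists and at a q of 1e-10 (2420 of KO and restored). That order reversed with equal list lengths (4737 of KO and restored), with sharing within 1 kb (3911) and with the stronger 50% (626).

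Regions in WT and restored but not KO, the opposite pattern, were often isolated: 317 of the 1331 (23.8%) were, against 20.7% of restored-only, 10.6% of WT-only and 6.99% of KO-only regions and 5.94% of the common ones. Of the 5 with the highest authors' fold in WT, the first was at chromosome 15 from 31097656 to 31098114, with 82 fragments in WT but 13 in the restored library. The others, at chromosome 11 from 17410113 to 17410416, chromosome 6 from 116482538 to 116482866, chromosome 14 from 110996694 to 110997030 and chromosome 5 from 127442756 to 127443110, had nearly equal heights in both libraries (44 and 34, 44 and 47, 42 and 45, and 40 and 38 fragments), and all 4 were isolated in both.

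Other regions separated WT from both libraries of the KO line, which a line difference or an effect of Sirt6 loss not reversed on its return can give. Of those in KO and restored but not WT, the 5 with the highest authors' fold in KO included neighbours on chromosome 3, from 96163972 to 96164389 and from 96177486 to 96178006, with 117 and 123 fragments in KO and 118 and 123 in the restored library. The others were on chromosome 5 from 37051901 to 37052776 (74 and 81 fragments) and from 14514314 to 14514911 (70 and 47), and on chromosome 11 from 68369613 to 68370260 (70 and 40). Of the regions in WT only, the first was on chromosome 11 from 50729213 to 50729799, with 66 fragments and an authors' fold of 14.1, and the second lay nearby, from 50872659 to 50873243, with 51 fragments. The other 3 were on chromosome 14 from 9119153 to 9119450, chromosome 10 from 55834735 to 55835582 and chromosome 2 from 105238772 to 105239393, with 45, 51 and 74 fragments.

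KO peaks that WT lacked were lost on restoration more often than KO peaks that WT shared, also within strength classes of the KO list. Of the former, 7411 of 13287 (55.8%, 54.9 to 56.6) had no restored peak, and of the latter 3023 of 26995 (11.2%, 10.8 to 11.6). In the weakest of 10 strength classes of the KO list the shares were 77.3% and 50.4%, in the sixth 24.7% and 7.76%, and in the eighth 4.55% and 0.452%. In the ninth class 0 of 79 and 0 of 3949 peaks were lost, for which the Clopper-Pearson upper limits are 4.56% and 0.0934%; a limit of 3 counts gives 3.80% and 0.0760%. The mean difference over 9 classes was 17.9 ± 0.915 percentage points (95% half-width, counting error only). A difference above 0 can arise without any effect of Sirt6, since the classes use the KO q alone. A site that misses the threshold in WT tends to be weaker than its KO q tells. The comparison therefore does not by itself show a return to the WT state. The mirror comparison, restored peaks without a KO peak by whether WT lacked or shared them, gave 11.03 ± 0.949 percentage points, a value added after the data were seen. With equal list lengths the values were 15.7 and 12.8. They were 20.4 and 9.88 at a q of 1e-10, and 7.66 and 3.71 with only the stronger 50% of each list counted as present.

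**Figure D3:**
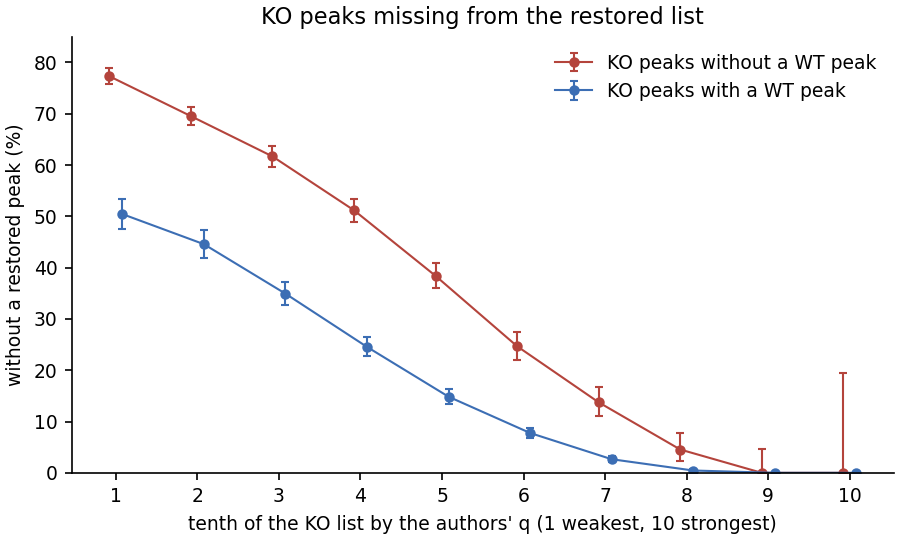
Share of KO peaks without a restored peak (y axis, percent) by strength class of the KO list, 10 equal classes of the authors' q (x axis, 1 weakest), for KO peaks without (red) and with (blue) a WT peak; bars are 95% Clopper-Pearson intervals, which cover counting error only. Red lies above blue from the weakest class (77.3% and 50.4%) to the eighth (4.55% and 0.452%), and both are 0 in the last 2 classes.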

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

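The test of pileups on unplaced sequences and that of peaks at the background level there were fixed before those values were seen. The other tests here, on isolated regions, strength classes of pileup and covariance, were chosen only after the result was seen.

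Peaks were also called on sequences of mm9 that have no assigned chromosome position, left out of the comparisons in the Results and used only in the tests of this part: 208 in WT, 196 in KO and 211 in the restored library. Merged, they made 243 regions, of which 157 (64.6%) were in all 3 lists. Their median pileups were 40.5, 41 and 41 fragments, and 22.6% of the WT peaks, 20.9% of the KO peaks and 21.3% of the restored peaks were at the background level of their library, against 8.81%, 7.23% and 8.62% on placed chromosomes.

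More KO peaks lacked a restored peak than the reverse, and common regions were lower in the restored library. If isolated regions are spikes of background, lower enrichment in that library is a candidate explanation: isolated common regions were higher in restored than in WT by 0.069 (log2, 0.051 to 0.095), while the others stood at -0.15. On unplaced sequences restored minus KO was 0.090 (0.030 to 0.14, single regions resampled), while common regions that were not isolated stood at -0.19. These signs met the rule fixed beforehand for lower enrichment. Unplaced sequences still do not decide it, since most of their peaks were above the background level, a condition that the rule did not hold. There KO minus WT was -0.076 (-0.14 to -0.044, single regions resampled), so the shift may belong to the KO library. A return of single sites to the WT state predicts a covariance of the KO minus WT and restored minus KO differences below counting error; it was -0.0523, below the lowest of 100 simulated draws (-0.0492), but the excess equals 2.10% of the variance between KO and WT, and extra noise in the KO library alone gives the same sign. Lower acetylation at all sites after Sirt6 returned cannot be told apart from lower enrichment: the restored minus KO median was below 0 in all 10 classes of pileup, -0.10 at its highest, both explanations predict this, and KO and WT, which had a median difference of 0.02, come from different lines.

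Regions of WT and restored but not KO were isolated in 23.8% of cases, and restored-only regions in 20.7%. A lower share of background reads in the KO library is a candidate explanation. Isolated regions common to the 3 lists were 0.12 higher in restored than KO (log2, 0.10 to 0.15) and differed by -0.051 between KO and WT. The value of -0.051 decides little, since the shorter fragments of KO (219 bp, against 229 bp in WT) also lower its pileup. Fragments of the restored library, at 222 bp, were close to those of KO. Sequences present in many copies may also contribute: peaks at the background level were at least 2.47 times as frequent on unplaced sequences, which often hold repeats, as on placed chromosomes. That comparison stands in for the regions themselves, whose sequence was not used here, and short unplaced sequences have little room for enriched surroundings. Acetylation that depends on Sirt6 at these sites was not tested, because KO has no value where it has no peak.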

How the results depend on the processing

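The comparisons of pileup, the mirror comparison of lost peaks and their alternatives were chosen after the data were seen; the other alternatives in this part were fixed before. Of 51 fixed alternatives 26 left counts within 1.5 times, or values within their interval, and 25 did not.

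At a q of 1e-10 the lists held 22374 (WT), 23621 (KO) and 20963 (restored) peaks. Then 5824 KO peaks lacked a WT peak, 4831 WT a KO peak, 4978 KO a restored peak and 2374 restored a KO peak; 3323 regions were in KO only and 2420 in KO and restored, and the loss difference was 20.4 points. Fewer peaks by construction lower these counts, and peaks that the other list held at a weaker q count as lacking there. With the stronger 50% as present, the counts in the same order were 1995, 1002, 688 and 292 peaks, 346 and 626 regions, with 90 in WT and restored, and the loss difference was 7.66. With sharing within 1 kb, 5761 KO peaks lacked a restored peak and 2551 the reverse, with 3461 regions in KO only and 856 in WT and restored. Equal list lengths gave 6326 KO peaks without a restored peak, 4240 KO-only regions and a loss difference of 15.7. The ratio of regions in KO but not restored to the reverse was 2.46, and 2.08 at a q of 1e-10. It was 1.07 with equal list lengths, which force it towards 1 by construction and so do not show why the KO list is longer. Chromosomes 1 to 19 alone moved none of the peak and region counts or loss differences beyond these limits, nor did overlap of 50% of a peak, which was run for peaks without a partner and the loss differences only.

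The restored minus KO median (-0.17) was -0.15 at a q of 1e-10, -0.19 without isolated regions and -0.30 when scaled to isolated regions, a scaling that moved it by over 0.1; KO minus WT was then 0.071. Scaling kept the sign of the chromosome 3, 4 and 5 differences. Promoter windows and gene lists, with all their alternatives, were not run. Depth limits single regions: near 40 fragments, differences under 1.55 times are within counting error.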

Other observations

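The tests of the chromosome-wide differences, the runs and the split of chromosome 4 were chosen after the result was seen.

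Regions of some kinds clustered along the genome. Runs of at least 4 neighbouring WT-only regions numbered 179, against a mean of 24.8 and a highest value of 41 in 1000 permutations within chromosomes. The longest had 16 regions, on chromosome 7 from 89078230 to 89484772, with a median WT pileup of 39 fragments, where the longest permuted run had 9. Runs of 14 regions lay on chromosome 12 from 9039426 to 9985668 and chromosome 8 from 94532082 to 96286482. Regions of KO and restored formed 55 runs (permuted mean 8.26, highest 17), KO-only regions 60 (22.8, highest 41), restored-only regions 4 (0.446, highest 3) and regions of WT and KO 3 (0.381, highest 3, so within the permuted range). Regions of WT and restored, with a permuted mean of 0.035, formed 0 runs, too few expected to tell. In KO and restored, 7 regions in a row lay on chromosome 4 from 88808914 to 89015823, with a median KO pileup of 51, and 7 KO-only regions lay on chromosome 17 from 84595388 to 84615923, lengths that permutation also reached.

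H3K56ac pileup differed between KO and WT by whole chromosomes. The values argue against an effect of Sirt6 that its return reverses, since the restored library undid 5.27% (0.429 to 9.04) of the shift of chromosomes 3 and 5 against the others. They also argue against depth or enrichment, since the shift was at least 0.18 (log2) in each of 10 classes of mean pileup. A copy number that differs between the lines may account for it. On chromosomes 3 and 5, common regions that were not isolated differed from those elsewhere by 0.46. Isolated regions, which DNA dose should also raise, differed by -0.022 (-0.091 to 0.10, 157 regions, single regions resampled). This decides little, because a higher dose also raises the local background and can take regions out of the isolated kind, and because isolated regions may collect reads from copies elsewhere in the genome. Copy number and line-wide differences in chromatin both stay open. So does an effect of Sirt6 loss that its return does not reverse, since genotype and line go together.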
